A study of Mus musculus with 6 samples.

How the data were processed

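Nuclei were taken from the frozen lumbar spinal cord of C57BL/6 mice that carry the SOD1G93A transgene, a mutant human superoxide dismutase that causes a motor neuron disease used as a model of amyotrophic lateral sclerosis. All mice were 110 days old. The 6 libraries fall into 2 groups of 3, PHD1+/+ and PHD1-/-, named PHD1+/+ replicate 1 to 3 and PHD1-/- replicate 1 to 3 after the labels. PHD1 is the protein made by Egln2. Each library was made with a droplet-based 3' kit, so a gene is read near the end of its transcript and each molecule is counted once by its unique molecular identifier (UMI).

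The deposited files hold raw UMI counts per gene and barcode, written by Cell Ranger 5.0.1 per the file headers. The submitters' processing notes name Cell Ranger 5.0.2, Scanpy 1.8.1 and the genome build mm10, and the source of the difference in version is not given in the sources used here. Whether reads in introns were counted is not given in the sources used here either. The deposited counts cover 32285 genes and 4 antibody tag features, and the 4 tag features hold 0 UMIs in every library. Every deposited barcode has at least 500 UMIs, so the barcodes had been filtered before deposit. The first barcode begins with AAACCTG in replicate 1 of both groups and with AAACCCA in replicates 2 and 3. Replicate 1 thus carries another kind of barcode list, a technical difference for which the labels give no batch. No cell annotation was used from the authors, and all classes were rebuilt from the counts. Gene positions come from the GENCODE annotation of GRCm38, the assembly also called mm10.

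Before any between-group test, barcodes were kept with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs. Doublets were marked with Scrublet in each library and removed. Scrublet marked 259, 151, 164 and 104 nuclei in replicates 2 and 3 of PHD1+/+ and of PHD1-/-, but 0 and 1 in replicate 1 of the same groups, under the 0.5% taken as the least for a working call, so doublets remain in those 2 libraries. Counts were normalised per nucleus and log-transformed, 2000 variable genes were chosen per library, and 30 principal components and 15 neighbours were used for Leiden clustering at a resolution of 1.0 in Scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9), with no integration across libraries. Clusters of neurons, of immune cells and of mixed astrocyte markers were clustered again on 1500 variable genes. A cluster was given an astrocyte-like, oligodendrocyte-like or other such name only from markers fixed beforehand, and the class names used in the text stand for these clusters. Neuron clusters were called excitatory where transmitter genes of excitatory neurons exceeded those of inhibitory neurons by a ratio of 2, and inhibitory where the opposite ratio was 8. Both ratios were set after the clusters were seen. Neuron clusters between them were kept apart as unresolved and held 821, 67 and 47 nuclei of PHD1+/+ replicates 1 to 3 and 632, 52 and 47 of PHD1-/- replicates 1 to 3. Clusters that stayed unnamed because they were rich in mitochondrial transcripts but carried astrocyte markers held 268, 3 and 2 PHD1+/+ nuclei against 46, 2 and 4 PHD1-/- nuclei. Other mitochondria-rich clusters held 714, 35 and 60 against 132, 18 and 65, and clusters of neurons mixed with glia held 584, 32 and 9 against 452, 45 and 20. A class entered the gene tests only if every library held at least 10 of its nuclei.

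UMI counts were summed per library and class and tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using TMM factors, filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 8 such comparisons, in all nuclei and in 7 classes, each of 3 libraries against 3. DESeq2 1.42.0 was run beside it. If no gene differed, a share of 0.05 of the tested genes would have an unadjusted p under 0.05. The counts of the main fit and of DESeq2 lie below that share in all 8 comparisons, so they are no sign of a difference. Nor do they show that there is none, since the spread in these fits takes in the difference between replicate 1 and the other libraries. Adjusted p-values in the text come from edgeR unless DESeq2 or camera is named. Levels are given in CPM, the UMIs of a gene scaled to a common library total. The total is that of the class for Egln2, Cyp2f2 and Sod1 and is corrected with the TMM factor for other genes. All fold changes are PHD1-/- against PHD1+/+ on the log2 scale, with the standard error (SE) of the fit. The p-values of single genes and of the permutation tests rest on the spread between libraries. Replicate 1 of both groups holds transcripts of both sexes, so a library may stand for more than 1 mouse. The labels speak of littermate pairs but do not state that the replicate number marks the pair, so the main test has no block. The numbers were then checked: same-numbered libraries deviated together from their group means, with pair correlations of 0.829, 0.636 and 0.523 for replicates 1, 2 and 3 in all nuclei, and every pair's correlation was over 0.1 in 7 of the 8 comparisons. The exception was endothelial cells, where replicate 3 gave 0.071. Libraries of different number among replicates 2 and 3 correlated too, at 0.394 and 0.484 in all nuclei. In astrocytes PHD1+/+ replicate 2 went more with PHD1-/- replicate 3 (0.352) than with PHD1-/- replicate 2 (0.306). The check thus shows that replicate 1 stands apart and cannot tell whether replicates 2 and 3 form pairs. The fit with the replicate number as a block is given as an alternative where it changes a call. With it, genes at an unadjusted p under 0.05 numbered 1362 of 15989 in excitatory and 1297 of 15725 in inhibitory neurons. In oligodendrocytes they numbered 1003 of 12598. These counts lie above the share of 0.05, as do, by less, those of all nuclei, astrocytes and OPC. The counts of microglia (376 of 8579) and endothelial cells (108 of 2961) lie below it.

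Apart from those stated in the text as chosen after values were seen, the tests, gene lists, cell type markers and alternative settings were fixed before the data were examined. The 21 lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, wherever at least 5 members were tested. They are interferon-stimulated genes, antigen presentation by MHC class I, HIF targets and glycolysis, NF-kB targets, reactive astrocyte, astrocyte homeostatic, disease-associated microglia, homeostatic microglia, disease-associated oligodendrocyte, myelin, cholesterol synthesis, ATF4 stress response, nuclear-encoded oxidative phosphorylation, synaptic, axon injury response, immediate early genes, mitochondrial genome, ribosomal protein, T and NK cell, border macrophage and monocyte, and sex-linked genes. Camera compares the genes of a list with all other genes. With the preset correlation its p-values rest on how many genes move alike. A small camera p is thus not evidence of that strength across libraries. A single value per library was compared by an exact two-sided permutation test, which for 3 libraries against 3 cannot go below 0.10. To compare shares of nuclei with a UMI, each nucleus was thinned to 1000 UMIs and shallower nuclei were left out.

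Genes were named by a fixed rule. It takes Egln2 in every comparison and, among genes past the threshold, the 12 with the smallest p in each direction. Where fewer than 20 genes passed, it adds the 5 genes with the smallest p in each direction that did not pass, as values. For each list described, it adds the members past the threshold and the 4 tested members with the highest mean level. Some genes that the rule takes are not reported here and were not replaced by others. Sex-linked genes are given as a group and predicted genes are counted but not named. The same rule was also applied to the genes past the threshold in the blocked fit, an extension chosen after the values were seen.

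The tests were checked on simulated counts for the real genes, with 200 genes changed. Without the block, a 4-fold change was recovered in 34.8% of the changed genes tested in all nuclei, 79.7% in astrocytes, 67.7% in oligodendrocytes, 68.2% in OPC, 20% in microglia, 52.3% in excitatory neurons, 54.5% in inhibitory neurons and 46.9% in endothelial cells. A 2-fold change was recovered in 0% in all nuclei, 1.64% in astrocytes, 4.48% in oligodendrocytes, 7.69% in OPC, 0% in microglia, 4.48% in excitatory neurons, 6.06% in inhibitory neurons and 1.72% in endothelial cells. With the block, a 2-fold change was recovered in 77.6% in excitatory neurons and 88.1% in inhibitory neurons. So in such counts the unblocked test had little reach below a 4-fold change and missed most 4-fold changes in microglia and all nuclei. The blocked test reached further with the same number of libraries. The unblocked counts were drawn from a single mean per gene with the spread of the unblocked fit. The blocked ones were drawn from the mean of each same-numbered pair with the spread of the blocked fit.

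Alternatives were DESeq2, RLE size factors in edgeR, no filter on low counts, the replicate block, leaving out each library in turn, keeping doublets, a minimum of 1000 UMIs per nucleus, the same number of nuclei per library and a clustering resolution of 0.5. Added after seeing the data were the kind of barcode list as a covariate (replicate 1 against replicates 2 and 3), replicates 2 and 3 alone, and mitochondria-rich clusters added to the astrocyte and cholinergic classes.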

Results

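Gene expression was measured in single nuclei of the lumbar spinal cord of SOD1G93A mice at 110 days of age, in 3 PHD1+/+ and 3 PHD1-/- libraries. The labels name PHD1, motor neurons and the interferon response of astrocytes, so the comparisons address what loss of PHD1, an oxygen-sensing prolyl hydroxylase encoded by Egln2, goes with in each cell class of this disease model. The deposited counts of PHD1+/+ replicates 1, 2 and 3 held 9174, 8028 and 5387 barcodes with 18901508, 32322447 and 24327572 UMIs. Those of PHD1-/- replicates 1, 2 and 3 held 6601, 7423 and 6145 barcodes with 14120298, 33794389 and 28565474 UMIs. After filtering, 22117 PHD1+/+ nuclei with 72540278 UMIs and 19789 PHD1-/- nuclei with 74358226 UMIs were left. Replicate 1 of both groups was shallower, with a median of 1363 UMIs per nucleus in PHD1+/+ and 1365 in PHD1-/-, against 2290.5 to 2902 in the other 4 libraries. Oligodendrocyte-like, neuron-like and microglia-like nuclei made up most of the tissue, with astrocyte-like nuclei at 3.01% ± 0.707 (SD, n = 3) of PHD1+/+ and 4.67% ± 2.84 (SD, n = 3) of PHD1-/- nuclei.

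Egln2 RNA was lower in PHD1-/- tissue but still present. Over all nuclei it reached 21.6 ± 7.04 CPM in PHD1+/+ (SD, n = 3) and 9.60 ± 0.522 in PHD1-/- (SD, n = 3), 44.4% of the PHD1+/+ mean, and every PHD1-/- library lay below every PHD1+/+ library (exact two-sided permutation p = 0.10, the smallest that 3 libraries against 3 can give). Per library these were 29.6, 18.8 and 16.4 CPM in PHD1+/+ replicates 1, 2 and 3 and 9.66, 9.04 and 10.1 in PHD1-/- replicates 1, 2 and 3. Summed over the libraries, 1514 UMIs gave 20.9 CPM in PHD1+/+ (exact 95% Poisson interval 19.8 to 21.95) and 710 UMIs gave 9.55 in PHD1-/- (8.86 to 10.3), intervals that cover counting error only. Egln2 (ENSMUSG00000058709) lies on the minus strand of chromosome 7 at 27158658 to 27166802 in GRCm38. The labels do not say which part of the gene was deleted, so reads from the 3' end may come from sequence outside the deletion.

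Mean Egln2 levels were lower in PHD1-/- in every class tested. In astrocytes it was 30.58 ± 16.004 CPM in PHD1+/+ against 6.02 ± 5.33 in PHD1-/- (SD, n = 3 each; exact permutation p = 0.10). PHD1-/- replicate 2 had 0 Egln2 UMIs among 353795 astrocyte UMIs, which allows up to 10.4 CPM (exact 95% Poisson limit). The means were 26.2 ± 6.50 against 13.6 ± 0.974 in oligodendrocytes, 21.7 ± 6.42 against 6.89 ± 3.43 in oligodendrocyte precursors (OPC), 17.9 ± 6.35 against 10.0 ± 2.65 in excitatory neurons and 17.8 ± 3.31 against 9.20 ± 2.38 in inhibitory neurons (SD, n = 3; exact permutation p = 0.10 in each of these 4 classes). They were 18.7 ± 9.59 against 7.45 ± 3.77 in microglia (exact permutation p = 0.30, n = 3) and 45.3 ± 25.4 against 8.86 ± 10.6 in endothelial cells (exact permutation p = 0.20, n = 3). In edgeR the log2 fold change was -1.17 in all nuclei (SE 0.26, adjusted p = 1), -0.94 in oligodendrocytes (SE 0.25), -0.83 in excitatory neurons (SE 0.31) and -0.98 in inhibitory neurons (SE 0.26). None of these passed the adjusted threshold, and with the replicate block Egln2 passed in inhibitory neurons alone (-0.99, edgeR adjusted p = 0.0218).

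**Figure D1:**
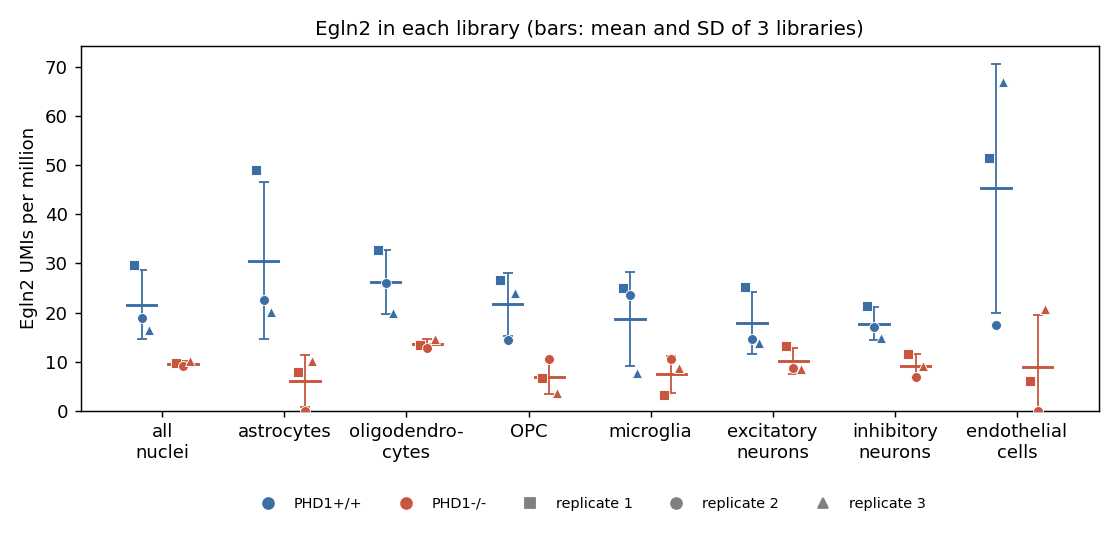
Egln2 CPM in each of the 6 libraries, for all nuclei and the 7 classes tested; points are libraries, bars the mean and SD of 3 libraries. Over all nuclei the 3 PHD1-/- libraries sit between 9.04 and 10.1 and the 3 PHD1+/+ libraries between 16.4 and 29.6.

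Motor neurons are the cells that die in this disease, and the share of the cholinergic nuclei that hold them was not shown to differ between the groups. No step parted motor neurons from other cholinergic neurons, so their own share was not measured. Cholinergic nuclei, the cluster marked by Chat that holds motor neurons, were 0.736% ± 0.327 of neuron nuclei in PHD1+/+ and 0.752% ± 0.0719 in PHD1-/- (SD, n = 3 each; exact two-sided permutation p = 1.0). They numbered 10, 28 and 22 in PHD1+/+ replicates 1, 2 and 3, or 0.359% (0.172 to 0.660), 0.949% (0.632 to 1.37) and 0.901% (0.565 to 1.36) of 2783, 2950 and 2443 neuron nuclei. In PHD1-/- they numbered 16, 24 and 17, or 0.690% (0.395 to 1.12), 0.830% (0.533 to 1.23) and 0.735% (0.429 to 1.17) of 2320, 2890 and 2314, all with exact 95% binomial intervals. Without PHD1+/+ replicate 1 the difference of the group means was -0.173 points and without PHD1-/- replicate 2 it was -0.0242, against 0.0153 over all 6 libraries. With 10 to 28 such nuclei per library a difference in motor neuron number is not excluded. The size of difference that could be detected was not tested.

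Of 17 classes, 0 differed in their share of nuclei at an adjusted threshold, by the exact permutation test or by edgeR (smallest edgeR adjusted p = 0.988). OPC had the smallest permutation p, with 2.43% ± 0.0649 of PHD1+/+ and 2.70% ± 0.111 of PHD1-/- nuclei (SD, n = 3; exact permutation p = 0.10, adjusted p = 1). Among nuclei with at least 1000 UMIs the OPC difference was -0.0461 points, with 2.87% ± 0.441 against 2.82% ± 0.105 (SD, n = 3; exact permutation p = 1.0). Oligodendrocytes made up 31.1% ± 4.43 against 32.8% ± 7.61 (SD, n = 3; exact permutation p = 0.80) and microglia 7.13% ± 1.28 against 6.66% ± 1.75 (SD, n = 3; exact permutation p = 0.60). Excitatory neurons made up 20.01% ± 5.19 against 19.5% ± 2.13, inhibitory neurons 14.6% ± 7.09 against 14.5% ± 5.32, and endothelial cells 1.15% ± 1.20 against 1.03% ± 0.941 (SD, n = 3 each). The smallest permutation p that 3 libraries against 3 allow is 0.10, so this test could not pass a 0.05 threshold.

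Over all nuclei, the RNA of Cxcl10, a chemokine induced by interferon, was lower in every PHD1-/- library. Its levels were 3.14, 2.32 and 3.56 CPM in PHD1+/+ replicates 1, 2 and 3 and 1.05, 0.78 and 1.04 in PHD1-/- replicates 1, 2 and 3 (log2 fold change -1.65, SE 0.30). It did not pass the threshold over all 19303 genes tested. Other genes with small p and lower values were Ndn, a gene of the imprinted Prader-Willi region (-0.69, SE 0.16), Ghitm (-0.64, SE 0.17) and Enho (-0.70, SE 0.20). Those with higher values were Cyp2f2, a cytochrome P450 (3.17, SE 0.81), the coagulation factor gene F5 (1.69, SE 0.50), Zfp981 (1.57, SE 0.48), Cct6b (0.73, SE 0.25) and Btn2a2 (1.04, SE 0.36). edgeR called 0 genes, with 96 at an unadjusted p under 0.05, and DESeq2 called 0, with 93 at an unadjusted p under 0.05. Both counts are below the share of 0.05 of the 19303 genes that would be reached if no gene differed. With the replicate block edgeR had 1148 at an unadjusted p under 0.05, above that share, and called 0.

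Several gene groups lay lower in PHD1-/- nuclei as a whole. Disease-associated microglia genes had negative values in 25 of 27 tested members (median -0.41, camera adjusted p = 8.94e-09; adjusted p = 0.56 with an estimated correlation). Homeostatic microglia genes lay lower as well, in 15 of 18 (median -0.11, camera adjusted p = 0.0167; adjusted p = 0.56 with an estimated correlation), as did border macrophage and monocyte genes in 9 of 9 (median -0.45, camera adjusted p = 2.15e-06; adjusted p = 0.512 with an estimated correlation). Reactive astrocyte genes were negative in 21 of 28 (median -0.25, camera adjusted p = 4.45e-05; adjusted p = 0.56 with an estimated correlation), where Cxcl10 alone was lower when adjusted over the list alone, and axon injury genes in 17 of 19 (median -0.40, camera adjusted p = 2.01e-06; adjusted p = 0.512 with an estimated correlation). ATF4 stress response genes were negative in 20 of 22 (median -0.17, camera adjusted p = 0.000494; adjusted p = 0.56 with an estimated correlation) and disease-associated oligodendrocyte genes in 11 of 16 (median -0.30, camera adjusted p = 0.0310; adjusted p = 0.56 with an estimated correlation). Lists that follow cytoplasmic RNA and RNA quality moved the same way: ribosomal protein genes were negative in 30 of 30 (median -0.50), oxidative phosphorylation genes in 27 of 28 (median -0.54) and mitochondrial genome transcripts in 12 of 13 (median -0.46; adjusted p = 0.56 for each of these 3 with an estimated correlation). Interferon-stimulated genes were negative in 46 of 62 (median -0.11, camera adjusted p = 0.0555; with the replicate block 0.0154; adjusted p = 0.783 with an estimated correlation). The camera adjusted p without PHD1+/+ replicate 1 was 0.0643 for disease-associated and for homeostatic microglia, 0.398 for reactive astrocyte (median 0.34), 0.805 for disease-associated oligodendrocyte (median 0.25), 0.144 for axon injury, 0.844 for ATF4, 0.0643 for oxidative phosphorylation (median 0.24) and 0.651 for mitochondrial genome genes, and ribosomal protein genes turned higher (median 0.27, camera adjusted p = 0.0391). Without PHD1-/- replicate 2 it was 0.611 for reactive astrocyte, 0.121 for border macrophage and 0.0526 for ATF4 genes, and without PHD1-/- replicate 3 it was 0.163 for ATF4 genes. Homeostatic microglia genes also lost the call without PHD1+/+ replicate 2 (0.846), PHD1-/- replicate 1 (0.109) and PHD1-/- replicate 3 (0.248), and disease-associated oligodendrocyte genes without PHD1+/+ replicate 2 (0.0746), PHD1-/- replicate 2 (0.117) and PHD1-/- replicate 3 (0.612). In replicates 2 and 3 alone, which form a batch of 2 libraries per group, each of the 10 lists past the threshold was lower by camera, with medians from -0.57 to -0.06. Within it the pairs differed: the mean of reactive astrocyte genes was -0.72 in pair 2 and 0.35 in pair 3, and that of border macrophage genes -1.50 and 0.10. Border macrophage nuclei themselves numbered 5, 26 and 11 in PHD1+/+ and 3, 1 and 20 in PHD1-/- replicates 1, 2 and 3.

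Astrocytes of PHD1-/- mice had lower values for interferon-stimulated genes, the group named in the title of the series. Only 15 members passed the count filter here, against 62 in all nuclei, so most of the list had no value in astrocytes. Of the 15 tested, 13 were negative, with a median log2 fold change of -0.38 and a mean of -0.42 (camera adjusted p = 1.81e-05 over the lists of this comparison; adjusted p = 0.54 with an estimated correlation). The mean log2 level of the list was 5.43 ± 0.232 in PHD1+/+ and 4.97 ± 0.494 in PHD1-/- libraries (SD, n = 3; exact two-sided permutation p = 0.20), a difference of -0.46 (SE 0.315), and it was lower in 3 of 3 same-numbered pairs, by -0.28, -0.78 and -0.32. PHD1-/- replicate 2, with 130 astrocyte nuclei, was the lowest. The best expressed members were Herc6 (-0.33, SE 0.25), Rnf213 (-0.38, SE 0.35), Stat2, a transcription factor of the type I interferon response (-0.25, SE 0.30), and Ifi27 (-0.28, SE 0.92). Of the 15 members 0 passed over all genes and 0 when adjusted over the list alone in edgeR. The fry test, which asks whether the list moves one way on balance, gave 0.138. In replicates 2 and 3 alone, without the shallower replicate 1, 17 of 21 tested members were negative (camera adjusted p = 1.70e-06; adjusted p = 0.849 with an estimated correlation). Leaving out 1 library at a time gave camera adjusted p from 3.31e-11 to 0.0130, and taking the same number of nuclei from each library gave 0.0844, at which the call was lost.

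The share of astrocytes with interferon-stimulated RNA lay within the spread of the libraries in both groups. Astrocytes thinned to 1000 UMIs carried UMIs of at least 2 list genes in 17.2% ± 5.79 of PHD1+/+ and 16.7% ± 5.88 of PHD1-/- nuclei (SD, n = 3; exact permutation p = 0.80). Oligodendrocytes thinned in the same way gave 9.04% ± 5.68 and 8.68% ± 5.83 (SD, n = 3; exact permutation p = 0.70) as a measure of the background. With at least 3 list genes the astrocyte shares were 6.97% ± 4.54 and 4.72% ± 3.22 (SD, n = 3; exact permutation p = 0.50), a difference of -2.25 points that became 0.372 without PHD1+/+ replicate 1, -4.08 without PHD1-/- replicate 1 and -1.05 without PHD1-/- replicate 2, and that lay at -3.63 without PHD1+/+ replicate 2 and -3.49 without PHD1+/+ replicate 3. By same-numbered pairs 1, 2 and 3 this difference was -3.83, -1.88 and -1.03 points (paired exact p = 0.25, the smallest that 3 pairs can give). With at least 2 list genes the pairs gave -0.68, -1.35 and 0.48 points. Unthinned astrocytes gave 39.1% ± 3.50 and 38.1% ± 6.14 (SD, n = 3; exact permutation p = 0.80) at median depths per library of 1244, 2338 and 2209 UMIs in PHD1+/+ and 1200, 2516 and 2540.5 in PHD1-/-. Thinning left out 49, 9 and 13 shallower PHD1+/+ and 109, 1 and 13 shallower PHD1-/- astrocytes of replicates 1, 2 and 3. The difference of -0.521 points became 2.77 without PHD1+/+ replicate 1, 2.03 without PHD1-/- replicate 2 and 0.142 without PHD1-/- replicate 3. It was -2.65 without PHD1+/+ replicate 2, -1.68 without PHD1+/+ replicate 3 and -3.73 without PHD1-/- replicate 1.

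**Figure D2:**
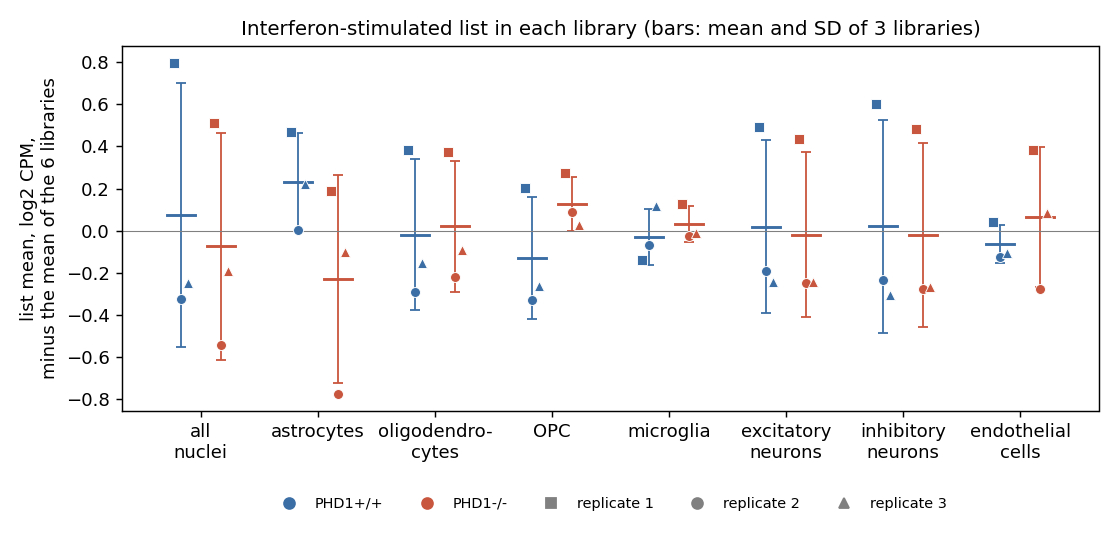
Mean log2 CPM of the tested interferon-stimulated genes in each library, minus the mean of the 6 libraries, for all nuclei and the 7 classes; points are libraries. In astrocytes the group means were 5.43 in PHD1+/+ and 4.97 in PHD1-/-, with PHD1-/- replicate 2 the lowest.

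Among single astrocyte genes, Tuba4a (-0.97, SE 0.35) and Tubb2a (-0.83, SE 0.30), which encode tubulins, Tor3a, an interferon-responsive torsin gene (-1.14, SE 0.37), Cstf2 (-1.24, SE 0.40) and Sec24c (-1.08, SE 0.38) had the smallest p among lower values. The transcription factor gene Sp1 (1.10, SE 0.31), the ciliary gene Ift140 (1.06, SE 0.32), St6gal2 (1.16, SE 0.38) and Ppp4r1 (0.80, SE 0.28) had small p among higher values. HIF targets and glycolysis genes, controlled by transcription factors that prolyl hydroxylases mark for destruction, were negative in 20 of 25 (median -0.26, camera adjusted p = 0.00543; adjusted p = 0.59 with an estimated correlation). Among them were the glycolytic genes Aldoa (-0.69, SE 0.42), Aldoc (-0.48, SE 0.37) and Pkm (-0.47, SE 0.34), and P4ha1 (0.11, SE 0.23). Reactive astrocyte genes were negative in 10 of 15 (median -0.14, camera adjusted p = 0.824) and homeostatic astrocyte genes in 12 of 18 (median -0.02, camera adjusted p = 0.824). Ribosomal protein genes (29 of 30 negative, median -0.43), oxidative phosphorylation genes (26 of 28, median -0.41), mitochondrial genome transcripts (9 of 9, median -0.50) and synaptic genes of neurons (17 of 24, median -0.20) were lower in the same astrocytes, each with a camera adjusted p at or below 0.00234 (adjusted p = 0.399 or more with an estimated correlation). These lists missed the camera threshold without PHD1+/+ replicate 1, at adjusted p = 0.427 for HIF targets, 0.366 for ribosomal protein, 0.222 for oxidative phosphorylation and mitochondrial genome and 0.0969 for synaptic genes. It was 0.0508 for HIF targets without PHD1-/- replicate 2 and 0.0642 for synaptic genes without PHD1-/- replicate 3. Replicates 2 and 3 alone gave HIF targets a median of -0.08 (camera adjusted p = 0.46), ribosomal protein genes -0.14 (0.232) and oxidative phosphorylation genes -0.05 (0.887). Neither edgeR nor DESeq2 called a gene (0 each), with 50 and 11 of the 7790 tested genes at an unadjusted p under 0.05. The 6 libraries held 221, 294 and 147 PHD1+/+ and 312, 130 and 448 PHD1-/- astrocytes.

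Interferon-stimulated genes centred near or above 0 in the other classes. The median log2 fold change was 0.02 in oligodendrocytes (14 of 24 tested members positive, camera adjusted p = 0.206 over the 6 classes), 0.27 in OPC (4 of 7, camera adjusted p = 0.0511), 0.04 in microglia (22 of 38, camera adjusted p = 0.382) and 0.33 in endothelial cells (8 of 10, camera adjusted p = 0.0734). It was -0.02 in excitatory neurons (10 of 27 positive, mean -0.06, though camera ranked the list as higher, adjusted p = 0.839) and 0.02 in inhibitory neurons (16 of 31, mean -0.07, camera adjusted p = 0.839). With an estimated correlation the adjusted p lay between 0.283 and 0.931. When adjusted over the lists of its own comparison, as in astrocytes, the list passed as higher in OPC (camera adjusted p = 0.0256; adjusted p = 0.579 with an estimated correlation; higher in 3 of 3 pairs). That OPC call was lost with the replicate block (0.132), in replicates 2 and 3 alone (0.215) and without any 1 of the 6 libraries (0.178 to 0.546). In each of these 6 classes 0 members passed over all genes, and Herc6 in OPC alone passed when adjusted over the list alone. Without PHD1+/+ replicate 1, 2 or 3 in turn, 2, 1 and 3 of the 6 classes passed the camera threshold.

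Oligodendrocytes had similar myelin RNA in both groups. Mbp (-0.02, SE 0.24), Mag (-0.05, SE 0.22) and Mog (0.18, SE 0.25), which encode major myelin proteins, differed by less than their standard errors, and myelin genes were negative in 12 of 18 (median -0.05, camera adjusted p = 0.755). Lower values with small p were those of Nyap1 (-1.42, SE 0.36), Scrt1 (-0.92, SE 0.25), the presynaptic scaffold gene Bsn (-1.26, SE 0.37) and the sodium channel gene Scn4b (-1.01, SE 0.30). The higher values were of Zfp300 (0.88, SE 0.30), Gnasas1 (0.92, SE 0.31), Zfp14 (0.59, SE 0.21), Zfp661 (0.97, SE 0.37) and Tmem132d (0.68, SE 0.26). Synaptic genes, markers of another cell type here, were negative in 17 of 26 (median -0.26, camera adjusted p = 0.000184; adjusted p = 0.58 with an estimated correlation). Oxidative phosphorylation genes (27 of 28 negative, median -0.43), ribosomal protein genes (30 of 30, median -0.31) and mitochondrial genome transcripts (13 of 13, median -0.34; adjusted p = 0.124 with an estimated correlation) were also lower by camera (adjusted p = 0.58 for the first 2 with an estimated correlation). Leaving out PHD1+/+ replicate 1 gave a camera adjusted p of 0.12 for synaptic and 0.125 for oxidative phosphorylation genes, and ribosomal protein genes turned higher (median 0.19, camera adjusted p = 0.0211). Without PHD1-/- replicate 2 it was 0.0589 for oxidative phosphorylation and 0.155 for ribosomal protein genes, and without PHD1-/- replicate 3 it was 0.141 for both. Mitochondrial genome transcripts stayed lower by camera whichever library was left out. Other lists of foreign cell types had lower means too. The mean differed by -0.32 for homeostatic astrocyte genes (SE 0.458; exact permutation p = 0.50) and by -0.27 for disease-associated microglia genes (SE 0.387; exact permutation p = 0.60). Disease-associated oligodendrocyte genes were negative in 11 of 15 (median -0.25, camera adjusted p = 0.0902; with the replicate block 0.00903). edgeR called 0 of 12598 genes, with 104 at an unadjusted p under 0.05, and DESeq2 called 0, with 58. Most replicate 1 oligodendrocytes of both groups lay in clusters of their own.

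OPC of PHD1-/- mice had lower values for HIF targets and glycolysis genes as a list, though 0 members passed in edgeR. HIF targets and glycolysis genes were negative in 16 of 20 (median -0.20, camera adjusted p = 0.0152; adjusted p = 0.579 with an estimated correlation), with Aldoa at -0.89 (SE 0.38), Pkm at -0.54 (SE 0.31), P4ha1 at -0.16 (SE 0.24) and Mxi1 at 0.12 (SE 0.32). Ribosomal protein genes (30 of 30 negative, median -0.35) and oxidative phosphorylation genes (25 of 27, median -0.47) lay lower by camera in the same nuclei (adjusted p = 0.579 for both with an estimated correlation). When PHD1+/+ replicate 1 was left out, the camera adjusted p was 0.788 for HIF targets and 0.869 for both other lists. Without PHD1-/- replicate 3 it was 0.146 for HIF targets, 0.14 for ribosomal protein and 0.328 for oxidative phosphorylation genes, and without PHD1-/- replicate 2 it was 0.144 for HIF targets. HIF targets in replicates 2 and 3 alone had a median of -0.09 (camera adjusted p = 0.243). Mitochondrial genome transcripts were lower in these nuclei as well, with a list mean that differed by -0.34 (SE 0.160; exact permutation p = 0.20) and was lower in all 3 pairs. Single genes with small p were Herc6, an interferon-stimulated ubiquitin ligase gene (1.58, SE 0.39), Phf6 (0.81, SE 0.25), the tachykinin gene Tac2 (1.95, SE 0.63), Mtf1 (1.28, SE 0.42) and Rmnd1 (1.19, SE 0.40) among higher values, and Rpl7a (-0.98, SE 0.28), Adipor1 (-1.21, SE 0.37), Pknox1 (-1.002, SE 0.32), Alg8 (-1.32, SE 0.43) and Sult4a1 (-1.26, SE 0.42) among lower ones. edgeR called 0 of 7826 genes, with 89 at an unadjusted p under 0.05, and DESeq2 called 0, with 20. With the replicate block edgeR called 1 gene, a predicted gene that was higher, and it did not keep its sign in replicates 2 and 3 alone.

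Microglia of PHD1-/- mice had lower values for disease-associated microglia genes, the group that rises when microglia respond to neurodegeneration. Of 27 tested members 23 were negative (median -0.22, camera adjusted p = 0.00399; adjusted p = 0.913 with an estimated correlation), among them Apoe (-0.34, SE 0.54), the cathepsin genes Ctsd (-0.28, SE 0.45) and Ctsb (-0.18, SE 0.32), and Cd9 (-0.22, SE 0.33). The list mean differed by -0.22 (SE 0.357, n = 3; exact permutation p = 0.60), with 0.17, -0.31 and -0.52 in pairs 1, 2 and 3. Without PHD1+/+ replicate 2 the list had a median of 0.05 (camera adjusted p = 0.40), with Apoe at 0.06, Ctsd at 0.11 and Ctsb at 0.04, and without PHD1-/- replicate 3 the camera adjusted p was 0.887. The median in replicates 2 and 3 alone was -0.36 (camera adjusted p = 7.33e-10). Homeostatic microglia genes split evenly, with 9 of 18 negative (median 0.01, camera adjusted p = 0.935). Synaptic genes of neurons were negative in 20 of 20 (median -0.40, camera adjusted p = 3.45e-07; adjusted p = 0.913 with an estimated correlation), and lower single genes with small p were Grin1, a glutamate receptor gene (-1.30, SE 0.36), Mllt6 (-1.14, SE 0.34), Rab3c (-1.09, SE 0.32), Map1a (-0.92, SE 0.28) and Chd5 (-1.17, SE 0.38). Higher values with small p were those of Fcsk (1.25, SE 0.38), Gopc (0.77, SE 0.28), Nbeal2 (1.05, SE 0.39), the cytokine gene Il1a (1.08, SE 0.40) and Tram2 (0.92, SE 0.34). Ribosomal protein genes were negative in 28 of 30 (median -0.23, camera adjusted p = 0.00399; adjusted p = 0.913 with an estimated correlation). Synaptic and ribosomal calls ended without PHD1+/+ replicate 1, at a camera adjusted p of 0.186 for synaptic and for ribosomal protein genes, and for the latter it was 0.0622 without PHD1-/- replicate 2 and 0.698 without PHD1-/- replicate 3. edgeR called 0 of 8579 genes, with 44 at an unadjusted p under 0.05, and DESeq2 called 0, with 14. Most replicate 1 microglia formed a cluster apart from those of replicates 2 and 3 in both groups.

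In excitatory neurons, the hypoxia-inducible growth factor gene Vegfa rose in PHD1-/- and 21 genes fell, among them the chaperone gene Hspa8 and the tubulin gene Tuba4a, once same-numbered replicates were compared with each other. With the replicate block edgeR called 26 of 15989 genes, 5 higher and 21 lower. Vegfa rose by 0.95 (SE 0.11, adjusted p = 0.00257), from 6.78, 22.64 and 24.55 CPM in PHD1+/+ replicates 1, 2 and 3 to 14.34, 44.19 and 46.00 in PHD1-/-, and in every library its level was higher in astrocytes (53.91, 137.26 and 152.14 against 59.93, 200.87 and 199.50). The other 4 that rose encode haemoglobin, a marker of red blood cells: Hbb-bs (1.03, SE 0.11, adjusted p = 0.00257), Hba-a2 (1.05, adjusted p = 0.0149), Hba-a1 (1.08, adjusted p = 0.0175) and Hbb-bt (1.33, adjusted p = 0.0271), pairs of near-identical genes between which reads can be shared. Hbb-bs stood at 126.20, 20.41 and 20.26 CPM in PHD1+/+ and 290.64, 47.35 and 29.89 in PHD1-/- replicates 1, 2 and 3. Oligodendrocytes had more of it in every library (282.50, 50.27 and 82.47 against 787.24, 184.59 and 82.86), so background RNA of another cell type may account for it. Vegfa had its higher level in astrocytes, a small part of the kept nuclei. They held 503470 of 14074710, 353795 of 32508245 and 1185845 of 27775271 kept UMIs in PHD1-/- replicates 1, 2 and 3. How much astrocytes add to the background RNA was not measured. For neither gene was background RNA tested, so expression by the neurons themselves is not shown. Among those that fell were the chaperone genes Hspa8 (-0.61, adjusted p = 0.00509) and Hsp90ab1 (-0.56, adjusted p = 0.0149), the cytoskeletal genes Tuba4a (-0.74, adjusted p = 0.00976), Actg1 (-0.58, adjusted p = 0.0143), Tuba1a (-0.48) and Tubb2a (-0.59), Selenok (-0.49), the neuropeptide gene Tac1 (-0.53), the ATP synthase gene Atp5b (-0.47) and the calmodulin gene Calm3 (-0.54), each at an adjusted p of 0.034 or less. In place of the 26, edgeR called 6 genes with the kind of barcode list as a covariate, 4 higher and 2 lower. In replicates 2 and 3 alone it called 1, which was higher, so the calls of these settings do not lean to lower values. All 26 kept their sign in replicates 2 and 3 and without the block, in libraries that also served to choose them.

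Without the block edgeR called 0 genes in excitatory neurons, with 77 at an unadjusted p under 0.05, and DESeq2 called 0, with 41. The unblocked fold change was 0.94 for Vegfa (SE 0.56) and 1.15 for Hbb-bs (SE 1.06), with replicate 1 of both groups apart from replicates 2 and 3 in level, and without PHD1-/- replicate 1 the unblocked value of Hbb-bs was -0.49. Genes with small unblocked p were Cep112it (0.92, SE 0.27), Atoh7 (0.74, SE 0.23), Apold1 (1.38, SE 0.43) and Stat5a (0.98, SE 0.32) among higher values and Slc25a10 (-0.86, SE 0.26), Tuba4a (-0.72, SE 0.22), Mad2l1bp (-1.02, SE 0.33), Clhc1 (-1.17, SE 0.39) and Ecel1 (-0.62, SE 0.21) among lower ones. HIF targets and glycolysis genes as a list showed no shift (18 of 31 negative, median -0.05, camera adjusted p = 0.955). Oxidative phosphorylation genes were negative in 27 of 28 (median -0.39, camera adjusted p = 7.73e-05; adjusted p = 0.639 with an estimated correlation), with Cox4i1 at -0.50 (SE 0.50), Ndufa4 at -0.70 (SE 0.46), Cox8a at -0.46 (SE 0.48) and Cox6c at -0.51 (SE 0.53). Ribosomal protein genes were negative in 30 of 30 (median -0.40; adjusted p = 0.63 with an estimated correlation). Synaptic genes, which excitatory neurons make themselves, showed no such shift (13 of 28 negative, median 0.02, camera adjusted p = 0.578). Glial lists were lower inside these neurons: myelin genes in 17 of 18 (median -0.39), homeostatic astrocyte genes in 13 of 17 (median -0.35) and disease-associated microglia genes in 21 of 23 (median -0.37; adjusted p between 0.63 and 0.664 with an estimated correlation for these 3 lists). Without PHD1+/+ replicate 1 the camera adjusted p was 0.33 for oxidative phosphorylation, 0.575 for ribosomal protein, 0.0871 for myelin, 0.851 for homeostatic astrocyte and 0.716 for disease-associated microglia genes. Without PHD1-/- replicate 2 it was 0.151 for myelin and 0.389 for homeostatic astrocyte genes. Without PHD1-/- replicate 3 it was 0.227 for oxidative phosphorylation, 0.951 for myelin and 0.531 for disease-associated microglia genes. All 5 lists were lower in replicates 2 and 3 alone by camera, with medians from -0.21 to -0.11.

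Inhibitory neurons had calls with the replicate block alone, nearly all of them lower. With it edgeR called 42 of 15725 genes, 2 higher and 40 lower. The neuropeptide gene Npy (-0.63, adjusted p = 0.00317), Ndn (-0.76, SE 0.09, adjusted p = 0.00252), Hspa8 (-0.65, adjusted p = 0.00317), Rnasek (-0.54), the oxidative phosphorylation gene Ndufa4 (-0.60, adjusted p = 0.00601), Tuba4a (-0.71, adjusted p = 0.0103) and Hsp90aa1 (-0.50, adjusted p = 0.015) were among those that fell, as were Spcs1 (-0.69), Actg1 (-0.51), Chchd2 (-0.53), Hsp90ab1 (-0.52), Tuba1a (-0.47) and Egln2 (-0.99). The 2 genes that rose were Foxp2, a transcription factor gene (0.58, adjusted p = 0.0281), and Cyp2f2 (3.54, SE 0.67, adjusted p = 0.0374). edgeR called 0 genes with the kind of barcode list as a covariate, with 1034 at an unadjusted p under 0.05, and 0 in replicates 2 and 3 alone, with 898, in place of the 42. The sign of all 42 was the same in replicates 2 and 3 and without the block, though these libraries also served to choose them. Excitatory and inhibitory neurons shared 13 of the genes that fell and 0 of those that rose, in sums from the same 6 libraries, so the 2 classes are not independent.

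Without the block edgeR called 0 genes in inhibitory neurons, with 61 at an unadjusted p under 0.05, and DESeq2 called 0, with 30. Small unblocked p were those of Cyp2f2 (3.88, SE 1.10), Pi16 (1.49, SE 0.43), Dnah14 (0.99, SE 0.30), Gins1 (0.90, SE 0.32) and Igfals (1.02, SE 0.38) among higher values, and of Ndn (-0.78, SE 0.20), Vax2 (-1.78, SE 0.48), Coa4 (-1.73, SE 0.49) and Magee1 (-0.66, SE 0.20) among lower ones. Ribosomal protein genes (30 of 30 negative, median -0.43), oxidative phosphorylation genes (25 of 28, median -0.35) and ATF4 stress response genes (13 of 17, median -0.21) lay lower by camera (adjusted p = 0.544 with an estimated correlation). Myelin genes (16 of 18, median -0.45) and homeostatic astrocyte genes (14 of 16, median -0.31), markers of other cell types, did so too (adjusted p = 0.603 and 0.544 with an estimated correlation). Without PHD1+/+ replicate 1 the camera adjusted p was 0.919 for oxidative phosphorylation, 0.176 for myelin and 0.774 for ribosomal protein, ATF4 and homeostatic astrocyte genes. Without PHD1-/- replicate 2 it was 0.171 for myelin and 0.452 for homeostatic astrocyte genes, and without PHD1-/- replicate 3 it was 0.591 for myelin genes. Synaptic genes did not (14 of 28 negative, median 0.00, camera adjusted p = 0.972).

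The genes that fell in inhibitory neurons were also lower in oligodendrocytes. Of the 40, all 40 had negative blocked values in oligodendrocytes, with a median of -0.40 against -0.50 in inhibitory neurons. Npy was an exception in size, at -0.00 in oligodendrocytes.

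**Figure D3:**
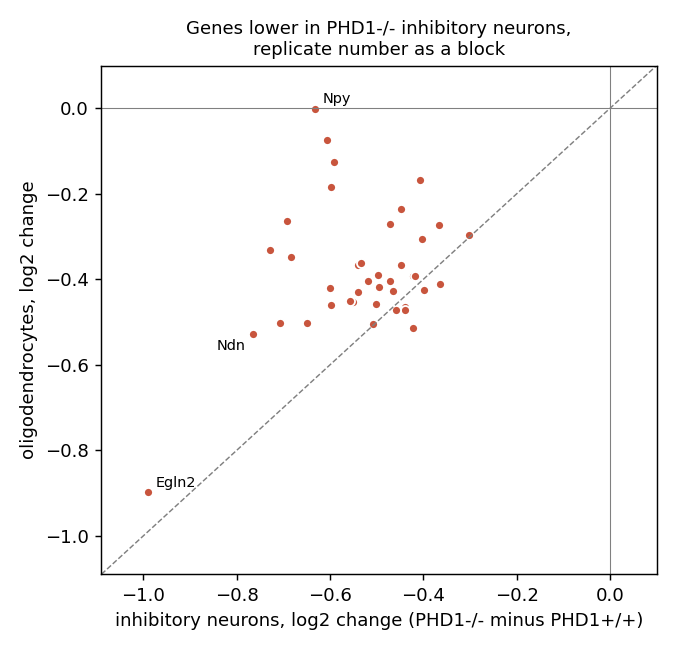
Log2 fold change with the replicate block of the 40 genes that fell in inhibitory neurons (horizontal axis) and of the same genes in oligodendrocytes (vertical axis); each point is a gene and the dashed line marks equal change. All 40 lie below 0 on both axes, with medians of -0.50 and -0.40, and Npy lies near 0 in oligodendrocytes.

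Endothelial cells, from 232, 33 and 26 PHD1+/+ and 133, 11 and 54 PHD1-/- nuclei, had lower values for synaptic genes of neurons. Lower single genes with small p were Cdh18 (-2.02, SE 0.59), the neuregulin gene Nrg1 (-1.80, SE 0.54), Dab1 (-1.67, SE 0.53), Kcnip4 (-2.16, SE 0.69) and Galntl6 (-2.14, SE 0.69), and synaptic genes were negative in 10 of 11 (median -0.43, camera adjusted p = 0.000434; adjusted p = 0.367 with an estimated correlation). Higher values with small p were those of Sept10 (1.52, SE 0.62), the oncostatin M receptor gene Osmr (1.26, SE 0.54), Mmrn2, an endothelial matrix gene (1.16, SE 0.51), the lactate transporter gene Slc16a1 (1.08, SE 0.48) and Nsmce2 (1.18, SE 0.53). Reactive astrocyte genes were positive in 7 of 8 (median 0.31, camera adjusted p = 0.00657; adjusted p = 0.367 with an estimated correlation), with Cp at 1.01 (SE 0.46), Vim at 0.15 (SE 0.44), Hspb1 at 0.21 (SE 0.54) and Gfap at -0.47 (SE 0.88). Disease-associated oligodendrocyte genes were negative in 2 of 6 (median 0.28, camera adjusted p = 0.0469; with the replicate block 0.0772; adjusted p = 0.709 with an estimated correlation). Without PHD1+/+ replicate 3 the camera adjusted p was 0.154 for reactive astrocyte genes and without PHD1-/- replicate 1 it was 0.327, and for synaptic genes it was 0.0502 without PHD1+/+ replicate 1. Disease-associated oligodendrocyte genes missed the threshold without any 1 of 4 libraries, PHD1+/+ replicates 2 and 3 and PHD1-/- replicates 1 and 2, with camera adjusted p from 0.0963 to 0.618. Ribosomal protein genes showed no shift (16 of 30 negative, median -0.01). edgeR called 0 of 2961 genes, with 25 at an unadjusted p under 0.05, and DESeq2 called 0, with 14.

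Across the 8 comparisons, the lists other than the interferon list gave 53 camera calls in 130 tests, 51 lower and 2 higher, and 0 with an estimated correlation (smallest adjusted p = 0.124). Ribosomal protein genes were lower in 7 of 8 comparisons, oxidative phosphorylation genes and mitochondrial genome transcripts in 6 of 8 each, disease-associated microglia genes in 5 of 8 and synaptic genes in 4 of 8. Reactive astrocyte genes were lower in 3 of 7, and ATF4 stress response genes in 3 of 7. Homeostatic astrocyte, axon injury and disease-associated oligodendrocyte genes were lower in 3 of 8 each. HIF targets, homeostatic microglia genes and myelin genes were lower in 2 of 8 each and NF-kB targets in 1 of 6. MHC class I antigen presentation (medians -0.21 to 0.14), cholesterol synthesis (-0.14 to 0.10), immediate early genes (-0.49 to -0.02), sex-linked genes (0.01 to 0.03) and T and NK cell genes (median 0.01, camera adjusted p = 0.521) gave no call. Without PHD1+/+ replicate 1 there were 20 calls, of which 6 were among the 53, without PHD1-/- replicate 2 there were 31 and without PHD1-/- replicate 3 there were 30. Of the 53 without PHD1+/+ replicate 1, 45 were lost, 2 reversed past the threshold and 30 kept their direction. In replicates 2 and 3 alone 39 of the 53 calls were kept, and all 52 of the lists with a value there had the same direction.

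Cyp2f2 lies next to Egln2, and its RNA was far higher in PHD1-/- libraries. Cyp2f2 (ENSMUSG00000052974) spans 27119909 to 27133660 on the plus strand of chromosome 7, 24998 bp from Egln2. It had 8, 5 and 3 UMIs in PHD1+/+ replicates 1, 2 and 3 and 63, 37 and 26 in PHD1-/-, a ratio of 7.68 in CPM (exact 95% interval 4.55 to 13.9, counting error only). In CPM per library that was 0.424, 0.164 and 0.130 against 4.48, 1.14 and 0.936, so PHD1-/- replicate 1 weighs most: the edgeR log2 fold of 3.17 was 2.17 without it and 3.78 without PHD1+/+ replicate 1. In inhibitory neurons 3 UMIs stood against 41, a ratio of 12.1 (3.87 to 61.2), and in excitatory neurons 4 against 36, a ratio of 8.65 (3.10 to 33.4). PHD1-/- replicate 1 was highest there too, with 7.93 CPM against 1.49 and 1.20 in replicates 2 and 3 in inhibitory neurons and 3.28 against 1.51 and 1.0008 in excitatory neurons, and without it the edgeR log2 fold in inhibitory neurons went from 3.88 to 3.04. Within 5 Mb of Egln2, 38 of 217 other genes tested in all nuclei (17.5%) had a blocked edgeR unadjusted p under 0.05, 9 with higher and 29 with lower values, against 1108 of 19067 genes (5.81%) elsewhere, an odds ratio of 3.44 (95% interval 2.41 to 4.91). This region was examined after the Cyp2f2 values were seen, and Cyp2f2 itself is among the 217 genes. The interval of the odds ratio treats genes as independent, though all are read from the same libraries.

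**Figure D4:**
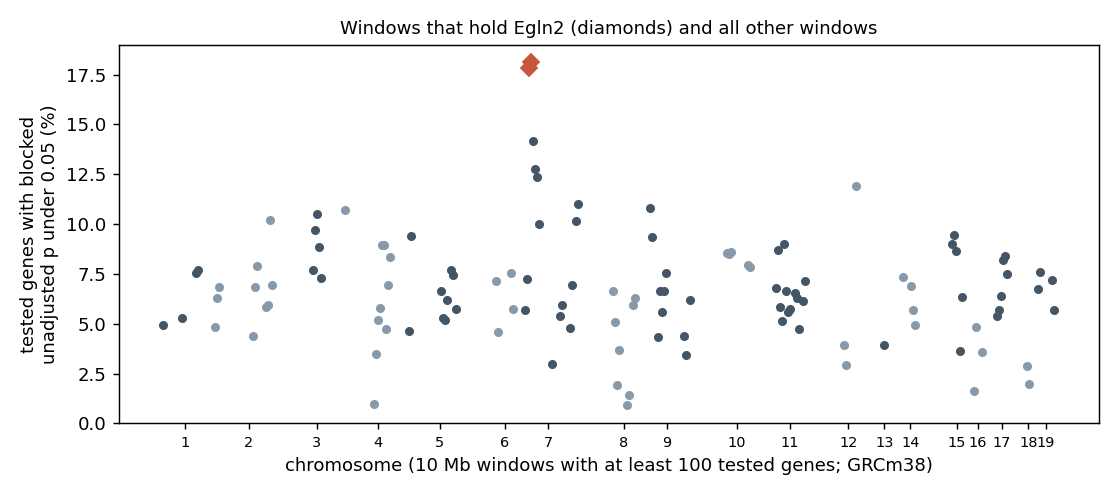
Share of tested genes with a blocked unadjusted p under 0.05 in all nuclei, in windows of 10 Mb along the genome (GRCm38) with at least 100 tested genes; each point is a window and the diamonds are the 2 that hold Egln2. The diamonds lie at 18.1% and 17.8%, above the other 119 windows, whose highest value was 14.2%. The next highest values, 14.2%, 12.7% and 12.3%, belong to windows between 30000001 and 50000000 on chromosome 7, beside those that hold Egln2.

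Sod1, the gene whose mutant human copy these mice carry, was 1526 ± 1801 CPM in PHD1+/+ and 888 ± 728 in PHD1-/- (SD, n = 3; exact permutation p = 0.70). Replicate 1 carries both means: the libraries stood at 3604, 414 and 560 CPM in PHD1+/+ and 1729, 476 and 459 in PHD1-/- replicates 1, 2 and 3. In replicates 2 and 3 the values of both groups overlap. The sources used here do not say whether reads of the human transgene count towards the mouse gene, so these values do not measure transgene dose.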

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

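The comparison with each other class was planned, while the test of free RNA, that of the genotype and the estimated correlation were chosen after the result was seen. The interferon-stimulated genes drew attention because their difference between PHD1-/- and PHD1+/+ was not alike in all classes, by a test of the difference itself within the same libraries. The change of the list mean in astrocytes minus that in another class was -0.56 for oligodendrocytes (SE 0.226), -0.75 for OPC (SE 0.368), -0.54 for microglia (SE 0.251), -0.43 for excitatory neurons (SE 0.232) and -0.40 for inhibitory neurons (SE 0.205). The camera adjusted p was 2.87e-06, 0.000191, 1.03e-05, 2.29e-05 and 0.000221, and with an estimated correlation the adjusted p was between 0.0915 and 0.093. The exact permutation p was 0.10 for OPC and microglia and 0.20 for the other 3 classes, where 0.10 is the smallest that 3 libraries against 3 can give. Without PHD1+/+ replicate 3 the differences were -0.23 for oligodendrocytes (camera adjusted p = 0.0748), -0.21 for excitatory neurons (0.069) and -0.23 for inhibitory neurons (0.0748). Endothelial cells had fewer than 5 members tested in common with astrocytes and gave no value.

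The lower interferon-stimulated genes of PHD1-/- astrocytes, among them Herc6, Rnf213 and Stat2, were weighed against a batch, free RNA and the genotype. Ribosomal protein, oxidative phosphorylation, mitochondrial genome and synaptic genes were lower by camera in the same astrocytes as well. A batch between replicate 1 and replicates 2 and 3 as the whole cause is argued against by replicates 2 and 3 alone, where the 13 of the 15 list members that were tested there as well, of either sign, had a mean of -0.47 (SE 0.125 over members), though over the 2 pairs the mean of -0.55 had an SE of 0.229 and did not clear the bound of -0.1 by 2 SE. Free RNA that reaches every class would lower the list in oligodendrocytes too, and the difference between the classes was -0.56, but it was -0.23 (SE 0.24) without PHD1+/+ replicate 3 and -0.32 (SE 0.25) without PHD1-/- replicate 2, so free RNA stays open. That the result should hold without each library was required only after it was seen. The genotype may account for the difference, but the exact permutation p of the list mean was 0.20, and it cannot be told apart from other differences between the mice with 3 libraries per group.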

How the results depend on the processing

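The kind of barcode list as a covariate, replicates 2 and 3 alone, the added mitochondria-rich clusters and the estimated correlation for astrocytes against other classes were chosen after seeing the data. Under settings that kept all 6 libraries or took 4, 109 values of the main results were the same, 12 moved, 1 reversed and 2 became weaker. Each value is a result under a single setting. A count of genes, lists or classes was taken as the same if equal or within 1.5-fold, and a test if it kept its direction and side of the threshold. Permutation results cannot go below 0.10, so their side of the threshold could not change. For the named genes 1102 values stayed on their side, 38 passed a threshold they had missed and 4 reversed.

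With the replicate block edgeR called 26 genes in excitatory neurons, 42 in inhibitory neurons and 1 in OPC in place of 0, and it changed no other gene count. It brought 8 list calls (interferon-stimulated in all nuclei, disease-associated microglia and axon injury in astrocytes, reactive astrocyte, disease-associated oligodendrocyte and axon injury in oligodendrocytes, oxidative phosphorylation in microglia, cholesterol synthesis in excitatory neurons) and ended 3 (interferon-stimulated in OPC, at a camera adjusted p of 0.132 within that comparison, NF-kB targets in excitatory neurons, at 0.210, and disease-associated oligodendrocyte in endothelial cells, at 0.0772). The block takes out the differences between replicate numbers by construction.

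Without the filter on low counts edgeR called 3 genes in astrocytes and 2 in OPC, 1 of the other classes passed for the interferon list and Mbp in oligodendrocytes was at 0.0095. In replicates 2 and 3 alone edgeR called 4 genes in astrocytes and 1 in excitatory neurons, and Ifi27 in astrocytes was at 0.0090, Aldoc in astrocytes at 0.041 and Hspb1 in endothelial cells at -0.20. With the barcode list as a covariate 6 genes were called in excitatory neurons and 0 in inhibitory neurons, which also had 0 in replicates 2 and 3 alone. The interferon list in astrocytes had a camera adjusted p of 0.0844 with the same number of nuclei per library and of 0.54 with an estimated correlation, which left 0 of the other lists and 0 of the differences between astrocytes and other classes. With doublets kept, 2 of the other classes passed for the interferon list. With the mitochondria-rich cholinergic cluster added, the difference in the cholinergic share was -0.0889 points. At a clustering resolution of 0.5 the cluster richest in cholinergic markers had 912 nuclei, 818 of them of replicate 1. Of the 912, 749 were neurons mixed with glia and 71 cholinergic at the main resolution, so no cholinergic share was taken there. For these settings the cause was not tested.

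Leaving out 1 library at a time, 84 of the main values were the same, 7 moved and 5 reversed, and 25 of the named values reversed against 747 that did not. The classes other than astrocytes that passed for the interferon list ranged from 0 to 3, calls of other lists from 20 to 74, and differences of astrocytes from other classes past the threshold from 3 to 6. The difference in the cholinergic share ranged from -0.173 to 0.122 points (-0.0242 without PHD1-/- replicate 2). That in the share of astrocytes with interferon-stimulated UMIs ranged from -3.73 to 2.77 points (2.03 without PHD1-/- replicate 2 and 0.142 without PHD1-/- replicate 3). In astrocytes Ifi27 ranged from -0.77 to 1.26 and Aldoc from -0.74 to 0.025. In oligodendrocytes Mbp ranged from -0.14 to 0.091, Mag from -0.19 to 0.032 and Mog from -0.039 to 0.30, and in OPC Mxi1 ranged from -0.24 to 0.32. In microglia Apoe ranged from -0.88 to 0.056, Ctsd from -0.60 to 0.11 and Ctsb from -0.38 to 0.035. In excitatory neurons Hbb-bs ranged from -0.49 to 2.56, Hba-a2 from -0.85 to 2.86, Hba-a1 from -0.88 to 2.92, Cox4i1 from -0.97 to 0.16, Cox8a from -0.86 to 0.18 and Cox6c from -0.92 to 0.25. In inhibitory neurons Tuba1a ranged from -0.97 to 0.0046, and in endothelial cells Gfap from -3.14 to 1.52 and Hspb1 from -0.60 to 0.69. Leaving out 1 library breaks a same-numbered pair, so batch differences enter these ranges by construction.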

Other observations

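The counts of other splits were planned, and the tests on neurons, with their count over other splits, and on the region of Egln2 were written after the values they start from were seen.

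Vegfa RNA and that of haemoglobin, a marker of red blood cells, had higher values in PHD1-/- in other classes than excitatory neurons as well. With the replicate block Vegfa was at 0.69 in oligodendrocytes (edgeR adjusted p = 0.544), 0.59 in inhibitory neurons (0.0629) and 0.41 in astrocytes, Hbb-bs at 1.17 in oligodendrocytes (0.489) and 0.91 in microglia, and Hba-a1 at 1.31 in oligodendrocytes (0.177) and 0.92 in microglia, none of them past the threshold. Replicate 1 of both groups held transcripts of both sexes, while replicates 2 and 3 held those of males. In PHD1+/+ replicate 1, 2503 nuclei had the X-inactivation transcript Xist alone, 2289 had Y-linked transcripts alone and 598 had both, against 1118 if the transcripts were spread independently. In PHD1-/- replicate 1 these were 3776, 750 and 394, against 795, and every other library had at most 3 nuclei with Xist alone. Egln2 stood at 27.8 CPM in nuclei with Xist alone and 28.7 in those with Y-linked transcripts alone in PHD1+/+ replicate 1, and at 9.91 and 11.7 in PHD1-/- replicate 1. Those 2 libraries therefore do not look like the tissue of 1 mouse each, and how many mice went into them is not given in the sources used here. These sex transcripts were examined after their values were seen.

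The 40 genes that fell in PHD1-/- inhibitory neurons with the replicate block, such as Hspa8, Tuba4a and Ndufa4, were set against free RNA and an action of the genotype on neurons. Free or cytoplasmic RNA that reaches every class is open: the same genes had a median of -0.404 in oligodendrocytes, all 40 of them lower, against -0.50 in inhibitory neurons and -0.0037 for all genes tested in oligodendrocytes. Under the 3 other splits that part every pair, however, the 40 lower genes with the smallest p in inhibitory neurons had medians of -0.28, -0.397 and -0.20 in oligodendrocytes, and 2 of the 3 reached, as the real split did, the bound of -0.24 set beforehand for this explanation, so genes chosen in this way move together across classes under other splits as well. An added fall in neurons is open, since the change in inhibitory neurons minus that in oligodendrocytes was -0.16 (SE 0.106), with -0.06, -0.37 and -0.04 in the 3 pairs, and cannot be told apart from 0 with so few pairs. A general effect of the genotype on every class was not tested.

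The higher Cyp2f2 RNA of PHD1-/- libraries was set against a chromosome region around Egln2 that differs between the groups, such as flanking sequence of another strain. The share of genes near Egln2 with a blocked unadjusted p under 0.05 was 3.01 times that elsewhere, which is consistent with such a region, and the strain in which the deletion was made is not given in the sources used here. A general shift of gene-dense regions is argued against, since 0% of the 119 other windows had as high a share, a test written after the share of the region was seen. The next highest windows, at 14.2%, 12.7% and 12.3%, lie between 30000001 and 50000000 on chromosome 7, and the first overlaps a window that holds Egln2. The raised share is thus not confined to 5 Mb around Egln2. On other chromosomes the highest share was 11.9%. Free RNA of another cell type is open: the CPM in PHD1-/- of 1.12 in oligodendrocytes, 1.502 in excitatory neurons, 1.85 in inhibitory neurons and 0.543 in microglia gave a ratio of 3.40 of highest to lowest, but the microglia value rests on 1 UMI. An effect of PHD1 itself, or of the deletion on the neighbouring gene, was not tested and may equally be the cause.

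The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. With 0 real calls all 10 of 10 splits had to give as many genes as the real one, so that count tells nothing. The highest other count was 0 in all nuclei, 1 in astrocytes, 0 in oligodendrocytes, 2 in OPC, 56 in microglia, 0 in excitatory neurons, 0 in inhibitory neurons and 55 in endothelial cells. The splits with 56 and 55 calls put both replicate 1 libraries on the same side, which points to a structure of the samples, the difference of replicate 1 from replicates 2 and 3. With the replicate block 4 splits part every pair, too few as well: 1 of 4 gave as many genes in excitatory neurons (26, highest other 1) and 1 of 4 in inhibitory neurons (42, highest other 1), while in oligodendrocytes another split gave 22 against 0 and in all nuclei another gave 16 against 0. For the interferon list in astrocytes 1 of 10 splits gave as small a camera p (minus log10 p of 5.65, highest other 2.90). For that list in the other classes 10 of 10 gave as many classes, as they must against 0 real ones (highest other 3). For the other lists 5 of 10 gave as many calls (53 calls, highest other 69).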
